A study of Mus musculus with 2 samples.

How the data were processed

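DNase-seq maps open chromatin by cutting nuclei with the nuclease DNase I and sequencing the ends of the released fragments. The libraries came from midbrain tissue of newborn mice of the strain B6NCrl (age 0 days, males and females pooled), and the labels give a single group of 2 biological replicates, prepared with a protocol for nuclei that names a crosslinking step. Each library has a biosample of its own in the labels, but both biosamples trace to one pooled donor entry of the strain, and nothing beyond the replicate numbers says that the animals were different. All p-values therefore describe these libraries, and part of the spread between them may be technical.

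For each library the authors deposited a list of peaks and a list of wider intervals called hotspots, on the mouse assembly mm10. Per the text deposited beside the lists, each was derived from the filtered alignment of 1 biological replicate, so peaks were called per library and not on pooled reads. The aligner, the peak caller, their versions and the calling limits are not given in the sources used here. Every peak is 150 bp wide and carries a whole-number signal deposited by the authors, whose definition is not given in the sources used here. It never exceeds the peak width and was not scaled between libraries. It was used only to rank, filter and describe peaks within a list. Each hotspot carries the −log10 of a q value as deposited by the authors, in which 100 stands for the strongest class, and a display score, also deposited, that follows the q value in steps and was not used in any test. The fields for the p and q values of single peaks hold no values. No read totals were given, so sequencing depth is unknown, and the number of peaks called is the only measure of how much each library yielded.

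Replicate 1 had 228440 peaks, of which 228203 were used after 215 on the mitochondrial genome or on unplaced sequences and 22 repeats of a position were set aside. Replicate 2 had 122838 peaks, of which 122593 were used after 221 and 24 were set aside in the same way. Hotspots numbered 206634 and 111593, and 206454 and 111394 of them lay on chromosomes 1 to 19, X and Y. Gene models came from GENCODE release M21 and the sequence from the RefSeq copy of the same assembly, and 0 intervals ran past the end of a chromosome. There were 21938 protein-coding genes on these chromosomes. Of the members of the 25 gene lists, 351 were matched by symbol and 1, the erythroid gene Ahsp, was not.

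Overlapping or touching intervals of both peak lists were merged into union regions, and a region was called replicated when it held a peak of each library. Overlap meant at least 1 bp. Chance overlap was estimated by shifting one list along each chromosome as if it were a circle, 1000 times for the values reported and 100 or 20 times for the alternatives, with a one-sided permutation p. Region midpoints were assigned to promoters (within 500 bp of any annotated transcription start site, TSS), then exons, introns and intergenic sequence, and compared with 1000 such shifts by a two-sided permutation p. Regions over 500 bp from any TSS are called distal. A gene was counted as having a replicated promoter peak when a replicated region lay within 500 bp of one of its TSSs. Shares carry 95% Wilson intervals, which cover counting error only.

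The 25 lists held markers of midbrain and other neurons, glia, blood vessels and blood, patterning genes of the forebrain, midbrain, cerebellum and Hox clusters, markers of unrelated organs and housekeeping genes. Lists were tested at promoters by two-sided Fisher's exact tests against all other protein-coding genes. A gene domain was the gene body with 10 kb on each side. The mean number of distal replicated regions per domain was compared with 10000 random lists of the same size matched on domain length in 20 bins. Between the libraries, both peak lists were first shortened to 122593 peaks by signal, and the log2 ratio of replicate 1 to replicate 2 peaks in the members' domains, with a pseudocount of 0.5 and relative to all protein-coding genes, was compared with 10000 random lists matched on the number of peaks in 20 bins. Both comparisons used two-sided permutation p-values. Consensus sequences of 20 transcription factor motifs were searched on both strands in the 150 bp about the midpoint of each distal region and in the 150 bp centred 1000 bp to either side, and compared by two-sided Fisher's exact tests, with 95% intervals of the odds ratio from its log standard error. P-values were adjusted by the Benjamini-Hochberg method over the 25 lists or the 20 motifs, with a threshold of 0.05. Genes and regions are not independent replicates.

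The groups, tests, lists, motifs, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, from each list, the 3 members with the most replicated regions in their domain and the first 3 by symbol without a replicated promoter peak. It further took the 10 genes with the most replicated regions per 100 kb, among domains of at least 30 kb with at least 5 regions, the 10 replicated regions with the highest mean rank of the 2 signals, the 5 genes with the strongest promoter peak in each library alone, and every motif. Any other gene was chosen after its values were seen, and is marked so.

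The alternatives fixed at that point were reciprocal overlap of 50%, the stronger 50% of each list, equal-length lists, hotspots in place of peaks, each library alone, promoter windows of 100 and 1000 bp, only the 5′ end of each gene, random lists matched on the CpG content of their promoters in 10 bins, domains with 50 kb on each side, assignment of distal regions to the nearest TSS, full lists in place of equal-length ones, and motif flanks 5000 bp away or matched on GC content. Another 7 were added after the data were seen. For the comparison between libraries they were the strongest 25% of each equal-length list, CpG-matched random lists, adjacent peaks within 1000 bp counted once, and runs of neighbouring genes in place of random genes for the Hox clusters, and each called list without the 1 or 2 members that differed most in the direction of the call. For gene domains, each called list was tested without the member with the most distal regions. The p-value of a shortened list took the place of that of the full list in the adjustment. A further 3 marker lists (cerebellar granule neuron, hindbrain and spinal cord, diencephalon; 46 genes) and 10 gene families, defined by their symbols, were also written after the main results were seen.

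Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9. Each procedure was first tested on simulated data. With a true peak overlap of 60% among 50000 simulated peaks, 60.2% was found. In 20 simulations over 21938 genes, the promoter test found 100% of lists planted with a peak at every promoter and 99% of those planted with a peak at 5% of promoters, against 60% elsewhere, and called 1.67% of the lists left alone. The domain test found 41% of lists planted 3-fold higher and 43% of those planted 3-fold lower and called 0.667% of the others, so a list that it did not call can still differ. The comparison between libraries found 100% of lists planted with a 3-fold ratio in either direction and called 1% of the others. A motif planted in 10% of 20000 windows was found in 10.0% of them, and 0 of 19 unplanted motifs were called. Results for some single genes are not reported here.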

Results

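DNase I-hypersensitive sites, stretches of DNA left open to the nuclease by regulatory proteins, were mapped in the midbrain of newborn mice (strain B6NCrl, day 0, both sexes pooled) in 1 group of 2 biological replicates. Replicate 1 yielded 228203 usable peaks of 150 bp covering 33.8 Mb, or 1.24% of the genome, and replicate 2 yielded 122593 covering 17.7 Mb, or 0.649%. The list of replicate 1 was therefore 1.86 times as long. The authors' signal per peak had a median of 44 in replicate 1 (quartiles 32 and 66) and 18 in replicate 2 (12 and 29), in units that were not scaled between the libraries. Hotspots covered 65.8 Mb in replicate 1 and 31.6 Mb in replicate 2. Read depth is unknown, so no value could be weighed by the number of reads behind it.

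The first comparison asked how far the 2 midbrain libraries located the same open sites. Most sites of the smaller library were open in the larger one: 79166 of 122593 replicate 2 peaks, 64.6% (95% Wilson interval 64.3 to 64.8), overlapped a replicate 1 peak. In the other direction 76494 of 228203 replicate 1 peaks, 33.5% (33.3 to 33.7), overlapped a replicate 2 peak. Shifted lists overlapped at 2.63% and 1.34%, so the observed overlap was 24.5-fold and 24.9-fold above chance (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Hotspots overlapped at 72.0% of replicate 2 and 33.5% of replicate 1, against 4.63% and 2.35% after shifting (permutation p = 0.001, again the smallest possible). The base pairs open in both libraries made up 0.210 of all base pairs in peaks of either (Jaccard index, 8.95 Mb shared) and 0.337 of those in hotspots (24.5 Mb). With both lists shortened to 122593 peaks, 53.4% of replicate 1 and 55.4% of replicate 2 peaks were shared.

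Strong sites were mostly shared and weak sites mostly were not. Among the strongest decile of replicate 2 peaks, 98.8% overlapped a replicate 1 peak, and 71.8% lay at promoters. The weakest decile overlapped at 5.68%. In replicate 1 the share went from 5.90% in the weakest decile to 92.9% in the strongest, of which 54.3% were promoter peaks. Peaks of replicate 1 without a partner had a median signal of 37, against 72 for shared ones, and in replicate 2 these medians were 11 and 24.

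**Figure D1:**
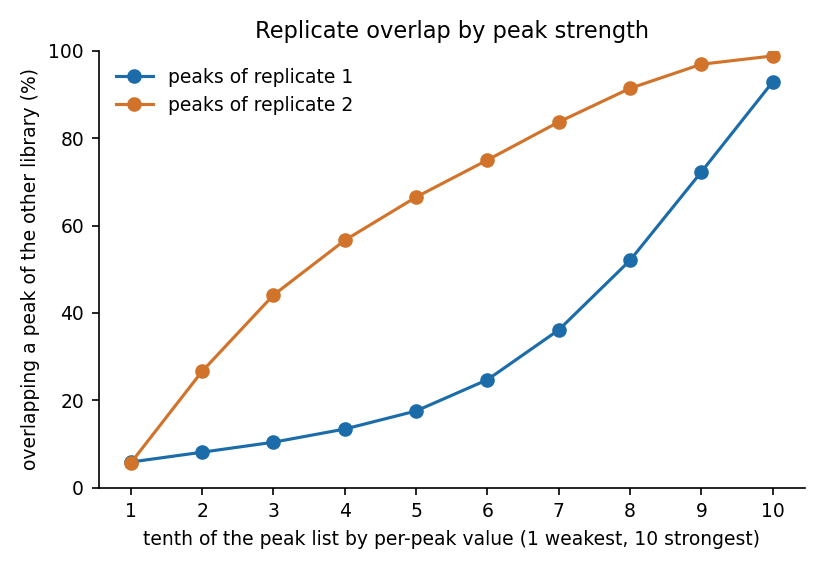
Share of peaks (y axis, %) that overlap a peak of the other library, by decile of each list ranked by the authors' per-peak signal (x axis, 1 weakest, 10 strongest). The curve of replicate 2 (orange) runs from 5.68% to 98.8% and that of replicate 1 (blue) from 5.90% to 92.9%.

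Merging gave 74833 regions with a peak in both libraries, with a median width of 170 bp and 14.1 Mb in all (0.519% of the genome). The 10 highest-ranked were all promoters. First came the promoter of Hjurp, which encodes a chaperone of centromeric histone H3 (chromosome 1, 88277556 to 88277725, mm10; signals of 149 and 125 in replicates 1 and 2). Next were Mdc1, a DNA damage response adaptor (146 and 94), Usp22, a histone deubiquitinase (146 and 91), Calr, a chaperone of the endoplasmic reticulum (148 and 88), and Sin3a, a corepressor scaffold (146 and 90). The remaining 5 of the top 10 were Map3k14, Selenof, Nudt2, Tcp1 and Txndc9, with signals of 145 to 147 and 88 to 97, and all 10 regions lay within 239 bp of a TSS. Across regions the 2 signals had a Spearman correlation of 0.772 and a Pearson correlation of 0.764 on the log2 scale, and regions are not independent replicates. Among the 52518 distal regions the Spearman value was 0.660.

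The location of open regions in the genome was compared with chance next. Promoters held 22315 of the 74833 regions, 29.8% (29.5 to 30.1), which is 8.95 times the 3.33% of shifted regions. Exons held 5.29% against 3.8% by chance, introns 34.3% against 40.8%, and intergenic sequence 30.6% against 52.1%. All 4 shares differed from chance (two-sided permutation p = 0.002, the smallest that 1000 shifts can give). Promoter regions had higher median signals (96 and 38) than distal ones (67 and 22). In replicate 1 alone the promoter excess was 4.82-fold and introns turned to a slight excess, 42.2% or 1.03-fold.

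Open regions were densest around Midn and 9 other genes. Midn, encoding the nuclear protein midnolin (chromosome 10, 80148272 to 80158368), had 18 replicated regions in its domain, 59.8 per 100 kb, against a median of 4.98 and a 95th percentile of 20.8 over the 5173 genes with domains large enough to rank. It was followed by Fam171a2 (48.9 per 100 kb), the histone demethylase gene Kdm6b (48.3), the Wnt signalling gene Dvl2 (47.3), Trim7 (45.6), Cbarp (42.8), the adhesion gene Pcdh1 (41.2), the RNA helicase gene Ddx39b (40.7), Dbn1, which encodes an actin-binding protein of dendritic spines (40.4), and A930004D18Rik (39.9). Cbarp neighbours Midn and their domains overlap, and all 10 genes had a replicated promoter peak.

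At promoters, 13391 of 21938 protein-coding genes, 61% (60.4 to 61.7), had a replicated peak. Replicate 1 had a promoter peak at 15105 genes and replicate 2 at 13733, and 6662 (30.4%) had none in either. The share followed CpG content: it was 1.14% in the decile of genes with the lowest ratio of observed to expected CpG around the TSS and 96.5% in the decile with the highest. A peak in replicate 1 alone was found at 1543 promoters, with a median signal of 41. The strongest were Gm10065 (120), Foxo6 (115), the cerebellin gene Cbln3 (112), the ETS factor gene Etv1 (111) and Pax5 (110), although a replicated region reached the Pax5 promoter window from outside it. A peak in replicate 2 alone was found at 171 promoters with a median signal of 10, led by the aromatase gene Cyp19a1 (38) and Olfr94 (32), with Alx1 (24) also among the strongest.

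The gene lists asked which cell types had their marker genes open at promoters. All 20 pan-neuronal genes had a replicated promoter peak (100%, against 61% of other genes), and so did all 17 housekeeping genes. Among the neuronal genes were Rbfox3, which encodes the neuronal antigen NeuN (signals of 100 and 37), and the neuronal transcription factor Myt1l (91 and 42). The housekeeping genes included Gapdh (131 and 72), Eef2 (124 and 72) and Ywhaz (134 and 75). Both lists were higher by Fisher's exact test (adjusted p = 0.000507 and 0.000947). Against random lists matched on promoter CpG content the pan-neuronal list stayed higher (permutation test, adjusted p = 0.0189) and the housekeeping list was no longer called (0.465).

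Promoters of other organs and of microglia were mostly closed. Of the 14 liver genes 0 had a replicated promoter peak (adjusted p = 2.31e-05, Fisher's exact test), among them Alb, the serum albumin gene, Apoa1 and Ahsg. One or 2 members were open in each of several lists by the same exact test: 1 of 14 microglia and macrophage genes (adjusted p = 0.000353), 1 of 13 pancreas and intestine genes (0.000507), 1 of 10 germ cell genes (Dazl, 0.00335), 2 of 13 lymphocyte genes (0.00281) and 2 of 10 epidermis genes (Krt1 and Krt10, 0.0395). Heart and skeletal muscle had 3 of 17 (Fisher's exact test, adjusted p = 0.00172), including the cardiac troponin gene Tnni3 (75 and 22). Other open members were Cela1, Lck, Rag1, Myl2 and Nppa, of which all but Lck were chosen for naming after their values were seen. Microglial genes such as Aif1, C1qa and C1qb, which encode a calcium-binding protein and complement subunits, had no replicated promoter peak. In replicate 1 alone, however, 7 of 14 microglial and 4 of 10 epidermis promoters had a peak and these calls were lost (adjusted p = 0.250 and 0.143, exact test). With random lists matched on CpG content, the calls of the liver (permutation test, adjusted p = 0.0612), heart and muscle (0.152), lymphocyte (0.210), microglia (0.236) and epidermis lists (0.285) ended, and those of pancreas and intestine (0.0129) and germ cells (0.00125) held.

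Patterning genes of other body regions were also mostly closed in the replicated set. Only Hoxa7 (86 and 44) among the 24 posterior Hox genes and Hoxb5 (98 and 38) and Hoxc4 (73 and 12) among the 15 anterior Hox genes had a replicated promoter peak, of which Hoxc4 was named after its values were seen (Fisher's exact test, adjusted p = 1.42e-07 and 0.000847). These genes set segment identity along the hindbrain and trunk. The forebrain patterning list had 5 of 16 (adjusted p = 0.0407, exact test), with Bcl11b (120 and 52) and Lhx2 (94 and 44) open and Emx1, Dlx5 and Dlx6 not. Against random lists matched on promoter CpG content, both Hox lists and the forebrain list were lower (permutation test, adjusted p = 0.00125 for each). Both Hox lists were also lower in replicate 2 alone. In replicate 1 alone, 14 of 15 anterior Hox promoters had a peak, which turned the list to a higher share that missed the threshold (adjusted p = 0.0932, exact test), and the posterior Hox list, at 11 of 24, lost its call (0.0515). The forebrain list was not called in either library alone, at 10 of 16 in replicate 1 and 9 of 16 in replicate 2 (exact test, adjusted p = 0.723 and 0.696), nor in hotspots (0.233) or the 1000 bp window (0.127).

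Midbrain patterning and GABAergic genes were open at about the rate of other genes, and dopaminergic genes had a lower share that missed the threshold. Replicated promoter peaks were found at 9 of 15 midbrain and isthmus patterning genes. Among them were Meis2 (106 and 28) and, chosen after their values were seen, the engrailed genes En1 (108 and 36) and En2 (112 and 52). No such peak was found at the isthmus growth factor genes Fgf8 and Fgf17 or at Pax2, where peaks of 71 and 17 did not overlap. The midbrain GABAergic list also had 9 of 15, with the glutamate decarboxylase genes Gad1 (65 and 25) and Gad2 (71 and 27) and the Gata cofactor gene Zfpm1 (134 and 61) open. Dopaminergic neuron genes had 6 of 17 (35.3%; Fisher's exact test, adjusted p = 0.0681). Kcnj6, a potassium channel gene (116 and 45), and Sox6 (103 and 38) were open, whereas Lmx1b, Ddc (48 and 13 in peaks that did not overlap), Aldh1a1 (33 in replicate 1 only) and Dlk1 (73 in replicate 1 only) were not. Nor were, also chosen after their values were seen, Th, which encodes the rate-limiting enzyme of dopamine synthesis and had no promoter peak in either library, and the dopaminergic regulator Nr4a2 (87 in replicate 1 only). Against random lists matched on promoter CpG content, all 3 of these midbrain lists were lower by a permutation test (adjusted p = 0.002 for dopaminergic neurons, 0.0373 for midbrain and isthmus patterning, 0.0225 for GABAergic neurons). The dopaminergic list was also called lower in the stronger 50% of the peaks (5 of 17, Fisher's exact test, adjusted p = 0.0389) and in the 100 bp promoter window (0.0481). In replicate 1 alone the dopaminergic share was 76.5% and the midbrain and isthmus share 86.7%, both above other genes but not called.

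The remaining neural and support lists did not pass the promoter test. Glutamatergic neuron genes had 12 of 15, with the receptor genes Grin2b (110 and 47) and Gria1 (88 and 43), and astrocyte genes 9 of 12, with Nfia (132 and 53) and Nfib (89 and 26). Neural progenitor genes had 11 of 16, including Pax6 (116 and 26) and the Notch effector Hes5 (119 and 45), and 16 of 16 in replicate 1 alone (adjusted p = 0.0148, exact test). Oligodendrocyte genes had 8 of 13, with the myelin genes Mbp (59 and 31) and Cnp (83 and 28) open and Mog and Mag not, and cerebellum and rhombic lip genes had 7 of 12. Cholinergic and serotonergic neuron genes each had 4 of 10, with Isl2 and the serotonin synthesis gene Tph2 (108 and 32) open and Chat and Fev not. Endothelial genes had 4 of 13 (exact test, adjusted p = 0.0681), with Pecam1, Cdh5 and Cldn5 all without a replicated promoter peak, erythroid genes 2 of 9 (0.0592) and meningeal genes 3 of 11 (0.0559). Against lists matched on CpG content the cholinergic and meningeal lists were lower (permutation test, adjusted p = 0.00333 and 0.0156). Several of these lists were also called lower with other settings. In the stronger 50% of the peaks these were the endothelial (1 of 13, Fisher's exact test, adjusted p = 0.000795), erythroid (0 of 9, 0.00107) and cholinergic lists (1 of 10, 0.00551), and in the 100 bp window the endothelial (2 of 13, 0.00805) and meningeal lists (1 of 11, 0.0042). The erythroid list was lower in replicate 1 alone (exact test, adjusted p = 0.0151), in the 1000 bp window (0.0369) and at the 5′ end (0.00144), the meningeal list at the 5′ end (0.0272) and the serotonergic list with reciprocal overlap (2 of 10, 0.0383).

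**Figure D2:**
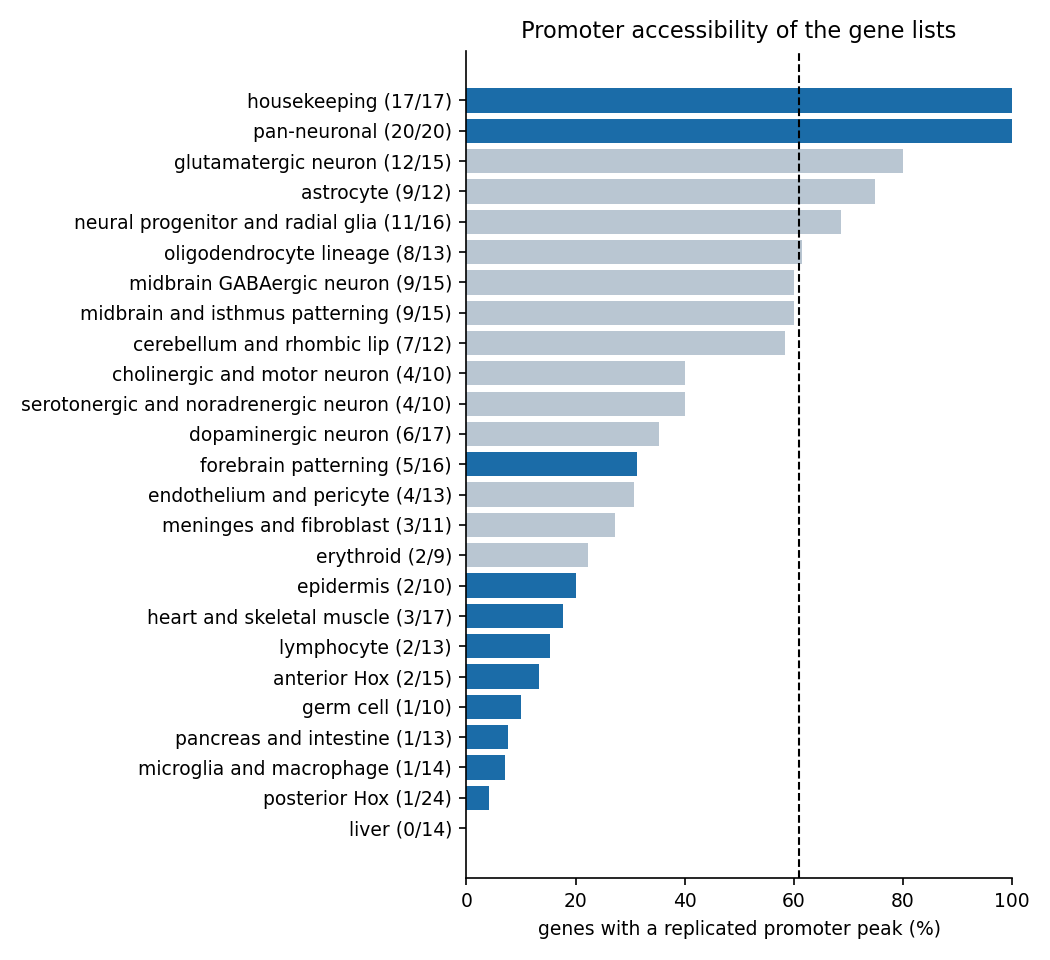
Share of genes with a replicated promoter peak (x axis, %) in each of the 25 gene lists, with the number of open and of all members beside the name; dark bars passed Fisher's exact test after adjustment and the dashed line marks the 61% of all protein-coding genes. The pan-neuronal and housekeeping lists reach 100% and the liver list stands at 0.

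Distal sites, which differ more between tissues than promoters do, were then counted in gene domains. Cerebellum and rhombic lip genes had 3.08 distal replicated regions per domain, against 1.00 in random lists of the same domain length (permutation p adjusted to 0.005, the smallest possible). Neural progenitor genes had 2.94 against 1.31 (permutation test, adjusted p = 0.045). Zic2, a zinc finger regulator of dorsal neural tissue (chromosome 14, 122475435 to 122479852), held 16 of the regions of the first list, and Barhl2, a homeobox gene, held 5. Among progenitor genes, Notch1 and the glutamate transporter gene Slc1a3 each had 7. No list was lower, even before adjustment. By unadjusted permutation p the pan-neuronal (8.70 against 4.40, p = 0.0198), oligodendrocyte (3.0 against 1.54, p = 0.0166), astrocyte (6.75 against 2.83, p = 0.0138) and GABAergic lists (3.53 against 1.87, p = 0.0454) also lay under 0.05, and none of these passed adjustment (0.099, 0.099, 0.099 and 0.189). The oligodendrocyte list was called higher in hotspots (3.15 against 1.38, permutation test, adjusted p = 0.0183) and in replicate 1 alone (8.77 against 4.23, 0.0167).

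Among members of these lists, Myt1l and Rbfox3 had 36 and 34 replicated regions in their domains, Nfib had 34 and Meis2 25. Dopaminergic genes had 3.24 distal regions per domain against 2.88 in random lists, and midbrain and isthmus genes 3.53 against 2.20 (permutation test, adjusted p = 0.844 and 0.243). The cerebellar call rested on a single member: without Zic2 the mean was 1.91 against 1.00 (random lists 0.36 to 2.00, permutation test, adjusted p = 0.243), inside the random range. Without Notch1 the progenitor mean stayed above its random lists, at 2.67 against 1.20 (0.53 to 2.13, permutation p = 0.0076), although the adjusted p rose to 0.095. These exclusions were added after the data were seen. The random lists kept their own top members, so a lost call does not show that the other members were ordinary. Both calls also ended when domains were widened to 50 kb on each side or when reciprocal overlap was required. When each distal region went to its nearest TSS, 7 lists were higher, among them the pan-neuronal, astrocyte, GABAergic, midbrain and isthmus and forebrain lists. Random lists for that setting were still matched on the length of the 10 kb domain. They were not matched on the distance to neighbouring TSSs, on which nearest-TSS counts depend, so these 7 calls may reflect gene spacing. The cerebellar call also ended in the stronger 50% of the peaks, at 0.917 regions against 0.667 (permutation test, adjusted p = 0.590). In replicate 1 alone cerebellar genes had 9.25 distal sites per domain against 2.33, and in replicate 2 alone 7.33 against 1.42, and both lists were called in either library.

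The last gene list comparison set the 2 libraries against each other, to ask whether the tissue samples differed in cell types or dissection. It compares libraries, not conditions. Domains of anterior Hox genes, which are active in the hindbrain and spinal cord, held 107 replicate 1 peaks and 30 replicate 2 peaks in the equal-length lists, a log2 ratio of 1.84 relative to all genes (permutation test, adjusted p = 0.005, the smallest possible; random lists −0.48 to 0.34). Of the 15 members, 13 had more peaks in replicate 1 and 0 had more in replicate 2. In the full lists, 11 of the 15 promoters had a peak in replicate 1 only, against 7.03% of all protein-coding genes. Hoxa2 (chromosome 6, 52162417 to 52164831) had a promoter signal of 96 in replicate 1 and no promoter peak in replicate 2. Hox domains overlap, so that a peak can count for several members; with each peak counted once there were 58 against 19. Posterior Hox genes had 67 and 80 peaks (log2 ratio −0.23, permutation test, adjusted p = 0.692). Of their 24 promoters, however, 10 had a peak in replicate 1 only, 1 in replicate 2 only and 1 in both, again in the full lists.

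Midbrain GABAergic domains differed the other way, with 109 replicate 1 and 199 replicate 2 peaks and a log2 ratio of −0.84 (permutation test, adjusted p = 0.020; random lists −0.44 to 0.47). The members were split, with 7 having more peaks in replicate 1 and 8 more in replicate 2. Most of the difference came from Gata3 (5 and 42 peaks in the equal-length lists) and, chosen after its values were seen, Tfap2b (6 and 51). Without Tfap2b the log2 ratio was −0.49 (permutation test, adjusted p = 0.290), and without both it was −0.085 (98 and 106 peaks, 0.808). These were also added after the data were seen, and again the random lists kept their own most different members. The anterior Hox list kept its call without the 2 members that differed most (1.59, permutation test, adjusted p = 0.005). The GABAergic list kept its call in full lists (−0.93, permutation test, adjusted p = 0.015) and in hotspots (−0.70, 0.030). Its call was lost when adjacent peaks within 1000 bp were counted once (log2 ratio 0.052) and in the strongest 25% of the peaks (−0.34). Against random lists matched on CpG content the log2 ratio of −0.84 stayed below the random range (−0.49 to 0.45, permutation p = 0.0042), with an adjusted p of 0.0525. The remaining 23 lists were not called, including dopaminergic neurons (132 and 113 peaks, log2 ratio 0.25) and forebrain patterning genes (60 and 103, −0.75, permutation test, adjusted p = 0.190). Full lists in place of equal-length ones were a choice fixed beforehand. Relative to all genes, the forebrain (−0.90, permutation test, adjusted p = 0.0414), midbrain and isthmus (−0.68, 0.0414), housekeeping (−0.58, 0.0414) and posterior Hox lists (−0.60, 0.0375) were then called lower in replicate 1. The epidermis list was called higher (0.92, permutation test, adjusted p = 0.0375). In full lists the log2 ratio over all genes was 0.69. The peaks of replicates 1 and 2 in these lists, in the same order, numbered 89 and 103, 188 and 187, 121 and 112, 85 and 80, and 47 and 15. The epidermis (1.04, permutation test, adjusted p = 0.030) and housekeeping lists (−0.70, 0.045) were called in hotspots too. In the strongest 25% of the peaks, an alternative added after the data were seen, the midbrain and isthmus list turned from −0.41 to 0.97 and was called higher in replicate 1 (permutation test, adjusted p = 0.00333), as were astrocyte genes (1.00, the same adjusted p). With adjacent peaks counted once, also added later, cerebellum and rhombic lip genes turned from −0.26 (98 and 120 peaks) to 0.65 and were called higher in replicate 1 (permutation test, adjusted p = 0.010).

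**Figure D3:**
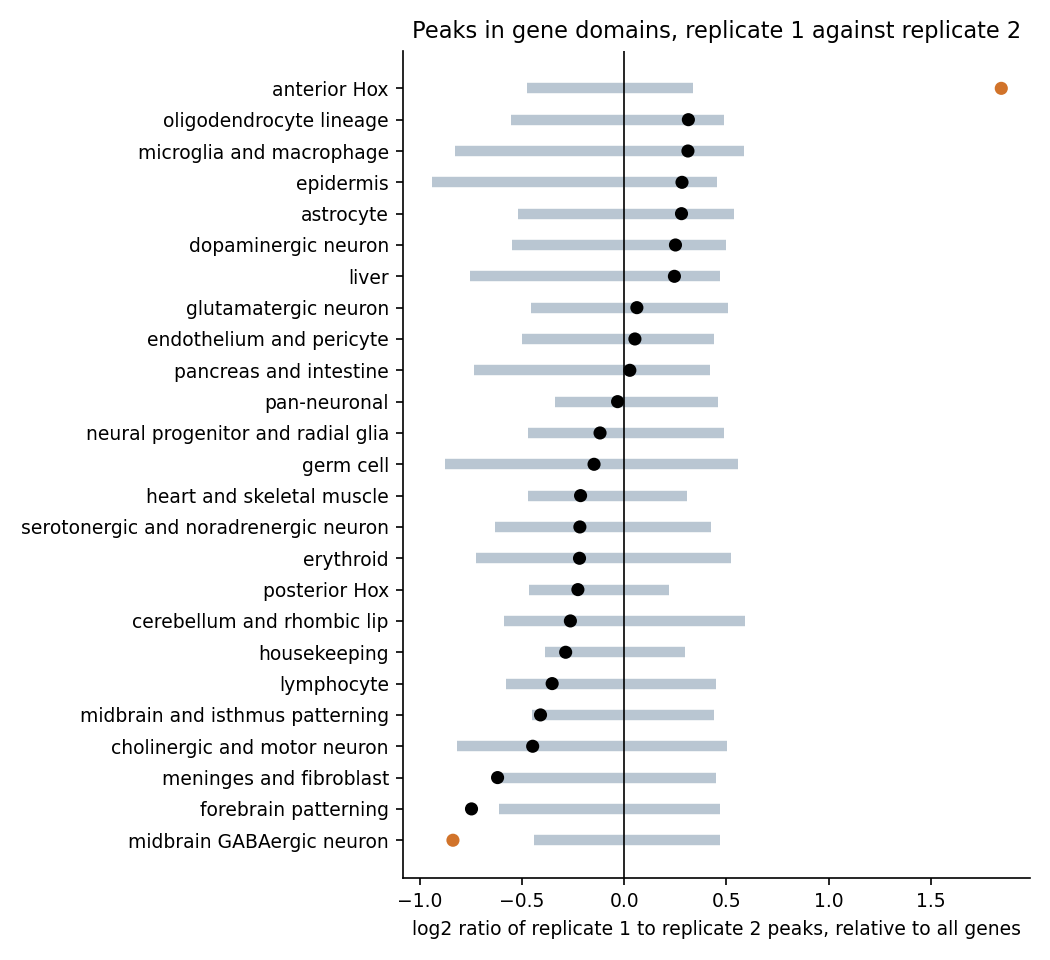
Log2 ratio of replicate 1 to replicate 2 peaks in the domains of each gene list, relative to all protein-coding genes (points; orange where the adjusted permutation p passed), with the central 95% of 10000 random lists (grey bars). Anterior Hox genes lie at 1.84 and midbrain GABAergic genes at −0.84, outside their grey bars.

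Motif searches asked which DNA-binding proteins have recognition sites in the distal regions. The site of CTCF, which anchors chromatin loops, was present in 9.73% of the 52518 distal regions and 0.143% of their flanks (odds ratio 75.4, 95% interval 64.1 to 88.7). NFI, a family active in glia and maturing neurons, followed with an odds ratio of 69.1 (16.9 to 282), from only 69 regions and 2 flanks. RFX, a family of ciliary gene regulators, had 50.2 (34.1 to 73.7). The order of NFI and RFX turned in the stronger 50% of the peaks (23.0 and 67.3). It also turned in hotspots, in replicate 2 alone and with flanks 5000 bp away, and held in the other settings. The site of REST, a repressor of neuronal genes outside neurons, had an odds ratio of 13.8 (6.55 to 28.9). The E-box read by proneural factors was found in 2.19% of regions and 0.812% of flanks (2.73, 2.5 to 2.99). NRF1 (3.68), ETS (2.00), MEF2 (1.84), SOX (1.46), SP/KLF (1.29), POU octamer (1.26) and AP-1 sites (1.11) were also more frequent, the last with an adjusted p of 0.00341, the largest of the 12 motifs called higher by Fisher's exact test.

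GATA (0.602, 0.535 to 0.679) and OTX sites (0.779, 0.733 to 0.828) were less frequent in the regions than in the flanks. The homeobox core TAATTA (0.980), HNF4 (0.981), PU.1 (1.04), p53 (1.02) and TEAD (1.02) were not called, and the HNF1 site was found in 0 regions and 0 flanks, which allows up to 3 regions. Regions had a GC content of 50.8% and flanks 46.2%. With flanks of the same GC content, ETS (1.17, adjusted p = 0.613, exact test) and SP/KLF sites (0.975, 0.822) were no longer called, the TAATTA core was more frequent (1.91, 3.66e-68) and PU.1 less frequent (0.739, 0.00227). Values from single libraries differed: the CTCF odds ratio was 31.4 in replicate 1 alone and 46.6 in replicate 2 alone, that of RFX 23.4 and 24.0, that of NFI 24.0 and 17.2, and that of the neurogenic E-box 4.59 and 2.00. SP/KLF sites were not called in replicate 2 alone (0.963, adjusted p = 0.472, exact test). In the stronger 50% of the peaks AP-1 and POU sites were not called, and in hotspots AP-1 and ETS sites were not called. TAATTA was less frequent in the stronger 50% (0.769), with reciprocal overlap (0.906) and with flanks 5000 bp away (0.941), and more frequent in hotspots (1.12) and in replicate 1 alone (1.42). p53 sites were called higher in each library alone (1.08 in replicate 1 and 1.09 in replicate 2), TEAD sites in each library alone (1.09 and 1.04) and in hotspots (1.06), and HNF4 sites lower in replicate 1 alone (0.860).

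**Figure D4:**
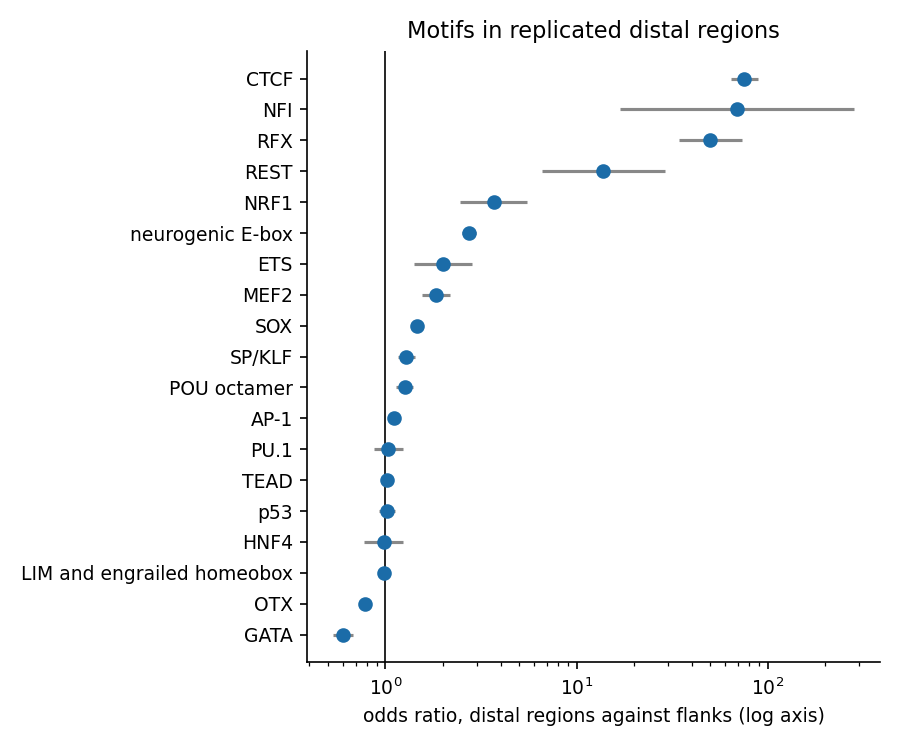
Odds ratio of each motif in replicated distal regions against their flanks (x axis, log scale; points with 95% intervals), with the line at 1 marking equal frequency. CTCF, NFI and RFX lie above 50, and GATA and OTX below 1.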

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

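No explanation was tested for the values in this part, and none of them rests on a test chosen after the result was seen. Both libraries held peaks on sequences that no comparison used. On the mitochondrial genome there were 31 peaks in replicate 1, with a median signal of 149 and a maximum of 150, and 30 in replicate 2, with a median of 124.5 and a maximum of 140. On sequences not placed on a chromosome there were 184 peaks in replicate 1, over 22 sequences, and 191 in replicate 2, over 27 sequences, of which 66 lay on a single one. The study has no control samples.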

How the results depend on the processing

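The strongest 25% of the peaks, adjacent peaks counted once, CpG-matched lists between libraries, runs of neighbouring genes and lists without their strongest members were chosen after the data were seen, and all other alternatives were planned. Of 1436 alternatives over 246 results, 1170 stayed the same and 266 did not. Staying the same meant keeping the direction and the side of the threshold, or lying within the spread. For the numbers of promoters, lists and motifs it meant lying within 1.5-fold. Of the changes, 29 became weaker, 42 stronger, 92 reversed and 103 moved, and 7 of the reversed results were past the threshold. Replicate overlap of peaks and of hotspots kept its calls in all 6 and 4 alternatives. The number of promoters with a replicated peak, which was not tested, stayed within 1.5-fold in all 8. Its share ran from 55.4% at the 5′ end alone to 68.9% in replicate 1 alone. Among named genes, 84 of 665 counts of regions moved. The cause of the changes was not tested, except that the single-library, stronger-50% and reciprocal settings change how many sites are counted. No paired analysis was possible because there is 1 group only. Read depth is unknown and limits what the shorter list of replicate 2 can show. The replicate agreement of signal, by Spearman and Pearson correlation, fell to 0.660 without regions within 500 bp of a TSS, and both were 0.735 for ranks in equal-length lists. With each library alone (lowest to highest value), introns held 37.2% to 42.2% of regions, 6 to 9 lists were lower at promoters, and promoter shares ran from 20% to 93.3% for anterior Hox, 58.3% to 100% for cerebellum and rhombic lip, 40.0% to 70.0% for cholinergic and motor neuron, 47.1% to 76.5% for dopaminergic neuron, 46.2% to 69.2% for endothelium and pericyte, 27.3% to 72.7% for meninges and fibroblast, 60% to 86.7% for midbrain and isthmus patterning and 61.5% to 76.9% for oligodendrocyte lineage, and were 80.0% in both for midbrain GABAergic neuron. Distal regions per domain ran from 1.20 to 3.27 for anterior Hox, 1.5 to 4.80 for cholinergic and motor neuron, 1.69 to 3.23 for lymphocyte, 2.82 to 3.09 for meninges and fibroblast, 2.5 to 6 for microglia and macrophage and 1.958 to 2.33 for posterior Hox, and odds ratios from 1.02 to 1.42 for the LIM and engrailed homeobox motif and 0.963 to 1.13 for SP/KLF. At promoters, hotspots gave 66.7% for midbrain GABAergic neuron and 61.5% for oligodendrocyte lineage, the stronger 50% 53.8% for oligodendrocyte lineage, and reciprocal overlap 58.3% for astrocyte and 53.8% for oligodendrocyte lineage. The 100 bp window gave 58.3% for cerebellum and rhombic lip, 60% for midbrain GABAergic neuron, 56.2% for neural progenitor and radial glia and 46.2% for oligodendrocyte lineage, the 1000 bp window 73.3% for midbrain GABAergic neuron and 61.5% for oligodendrocyte lineage, and the 5′ end alone 53.8% for oligodendrocyte lineage. CpG-matched lists left 1 list higher and put neural progenitor and radial glia, at 68.8%, below its random lists. In gene domains, hotspots gave 1.31 for pancreas and intestine. The stronger 50% left 1 list higher and gave 1.00 for liver, 0.769 for lymphocyte and 1.08 for pancreas and intestine, and reciprocal overlap left 0 lists higher (6 before adjustment, by the permutation test) and gave 1.21 for liver. Domains with 50 kb on each side left 0 lists higher (3 before adjustment) and gave 4.88 for dopaminergic neuron, 4.44 for erythroid, 3.75 for forebrain patterning, 4.10 for germ cell, 4.21 for liver, 4.23 for lymphocyte, 4.62 for pancreas and intestine and 3.20 for serotonergic and noradrenergic neuron. Without the member with the most regions, the cerebellum and rhombic lip list fell to 1.91 and the neural progenitor and radial glia list to 2.67, and both calls ended; the second stayed above its random lists (0.53 to 2.13). The nearest TSS gave 7 higher lists and 2.20 for cholinergic and motor neuron, 1.86 for liver, 2.73 for meninges and fibroblast, 2.14 for microglia and macrophage and 0.375 for posterior Hox. Between libraries, full lists gave 2 higher and 5 lower lists and log2 ratios of −0.021 for astrocyte, 0.51 for cholinergic and motor neuron, −0.19 for glutamatergic neuron, −0.0041 for pancreas and intestine and 0.0077 for serotonergic and noradrenergic neuron. Hotspots gave 2 higher and 2 lower lists and 0.56 for cholinergic and motor neuron, −0.11 for glutamatergic neuron and 0.094 for serotonergic and noradrenergic neuron. The strongest 25% gave 3 higher and 0 lower lists (1 lower before adjustment) and 0.46 for cerebellum and rhombic lip, 0.39 for cholinergic and motor neuron, −0.70 for epidermis, 0.14 for erythroid, 0.34 for forebrain patterning, 0.032 for germ cell and for meninges and fibroblast, −0.52 for liver, −0.24 for microglia and macrophage, 0.97 for midbrain and isthmus patterning, 0.39 for neural progenitor and radial glia, −0.028 for oligodendrocyte lineage and −1.55 for pancreas and intestine. The midbrain GABAergic list fell to −0.49 without Tfap2b and −0.085 without Tfap2b and Gata3 and its call ended, and the anterior Hox list kept its call at 1.68 and 1.59 without the 1 and 2 members that differed most. CpG-matched lists between libraries gave 0 lower lists (3 before adjustment). Adjacent peaks counted once gave 2 higher and 0 lower lists (0 lower before adjustment too) and 0.65 for cerebellum and rhombic lip, −0.043 for endothelium and pericyte, 0.020 for heart and skeletal muscle, 0.052 for midbrain GABAergic neuron, 0.17 for midbrain and isthmus patterning, 0.16 for neural progenitor and radial glia, 0.25 for pan-neuronal, −0.084 for pancreas and intestine and 0.15 for posterior Hox. For motifs, hotspots gave 1.12 for LIM and engrailed homeobox, the stronger 50% 0.844 for PU.1 and 0.951 for p53, reciprocal overlap 1.09 for HNF4 and 0.979 for p53, and flanks 5000 bp away 0.939 for PU.1 and 0.987 for TEAD. Flanks matched on GC content gave 1.01 for HNF4, 1.91 for LIM and engrailed homeobox, 0.739 for PU.1 and 0.975 for SP/KLF.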

Other observations

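The gene families, the 3 marker lists and the base composition test below were chosen only after the main results were seen, as were the alternatives for the comparison between libraries other than full lists and hotspots. Promoters of sensory receptor families were nearly all closed in the replicated set. A replicated promoter peak was found at 7 of 1135 olfactory receptor genes (0.617%, 95% Wilson interval 0.299 to 1.27) and 3 of 331 vomeronasal receptor genes (0.906%, 0.309 to 2.63). In single libraries, 75 olfactory promoters had a peak in replicate 1 and 21 in replicate 2, and 14 and 12 vomeronasal promoters did. The median ratios of observed to expected CpG of these families were 0.153 and 0.116. In the deciles of all genes that hold these ratios, 4.01% and 1.14% had a replicated promoter peak. Those deciles include members of the families themselves, so they cannot show whether the shares stand out from other genes with similar promoters. Families were not matched on CpG content. Of the keratin genes, 5 of 53 (9.43%) had a replicated promoter peak. Families used by every cell were open, with 78 of 78 mitochondrial ribosomal, 74 of 77 cytosolic ribosomal and 38 of 40 proteasome subunit genes. Zfp zinc finger genes (338 of 394, 85.8%), clustered histone genes (54 of 67, 80.6%, adjusted p = 0.00106, Fisher's exact test) and voltage-gated potassium channel genes (31 of 40, 77.5%, adjusted p = 0.0347, exact test) were also higher than other genes. In the deciles of all genes that hold their median CpG ratios, however, 87.3%, 95.9% and 91.0% had such a peak. The shares of these families were not above those of their deciles. Clustered protocadherins, adhesion molecules that give neurons individual identities, were lower at 21 of 57 (36.8%, adjusted p = 0.000393, Fisher's exact test), although 51 of these promoters had a peak in replicate 1 and 23 in replicate 2.

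Replicated regions were densest on chromosome 11, with 43.9 per Mb, and least dense among autosomes on chromosome 14, with 23.6. Chromosome X had 10.4 per Mb and chromosome Y 0.229. Across the 19 autosomes, which are not independent replicates, regions per Mb and protein-coding genes per Mb had a Spearman correlation of 0.879. In the equal-length lists, chromosome X held 2015 peaks of replicate 1 and 3007 of replicate 2, and chromosome Y 21 and 117. In the full lists chromosome X held 5226 of 228203 replicate 1 peaks and 3007 of 122593 replicate 2 peaks, and chromosome Y 42 and 117. The X count of replicate 1 was therefore lower only after its list was cut by signal. As a share of all peaks, however, chromosome X was already slightly lower in its full list, and so was the Y count itself. Several regulators had more peaks in the shorter full list of replicate 2, among them, chosen after their values were seen, Sox2 with 6 in replicate 1 and 39 in replicate 2 and Thra with 27 and 58, and, under the rule for named genes, Pax6 with 18 and 40.

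Anterior Hox domains held more replicate 1 peaks. Weak peaks of the longer list do not account for this, since the log2 ratio in the strongest 25% was 1.05 (random lists −0.57 to 0.32), nor do overlapping domains, since with each peak counted once it was 1.61 (random runs of neighbouring genes −0.76 to 0.38). Cerebellar tissue in the replicate 1 sample stays open, since the lists that bear on it went apart. A list of 16 other genes, written as granule neuron markers, had a log2 ratio of 0.62 (random lists −0.42 to 0.51, permutation p = 0.0104, adjusted over 3 lists 0.0312). More replicate 1 peaks were found at 12 of 16, including Sema6a (25 and 11) and Zic4 (27 and 16 peaks in the equal-length lists). Rora held the most peaks, 63 of 263 and 33 of 174, and the list was not tested without it. The planned cerebellum and rhombic lip list gave −0.26 (−0.59 to 0.59), −0.37 in full lists and −0.33 in hotspots, but 0.65 with adjacent peaks counted once and 0.46 in the strongest 25% (−0.57 to 0.46). Of the genes in the granule neuron list 14 had promoter peaks in both libraries, and Zic4 and Zic5 neighbour Zic1 and Zic2 of the cerebellum list. Hindbrain tissue stays open too, as 14 hindbrain and spinal cord genes gave −0.15 (−0.58 to 0.54). Apart from tissue in the samples, no biological explanation was tested.

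Midbrain GABAergic domains held more replicate 2 peaks. This may come from rows of adjacent peaks in replicate 2, since the log2 ratio was 0.052 with peaks within 1000 bp counted once (random lists −0.31 to 0.39), or from its weak peaks, since it was −0.34 in the strongest 25% (−0.46 to 0.40), where only 20 and 26 peaks were left. The list stayed below its random lists in full lists (−0.93, random −0.46 to 0.60) and in hotspots (−0.70, random −0.39 to 0.61). In hotspots the counts themselves were nearly equal, 162 and 168, and were set against a log2 ratio of 0.65 over all genes. Housekeeping genes were also called lower relative to all genes in both settings, at −0.58 in full lists (121 and 112 peaks) and −0.70 in hotspots (93 and 96). Diencephalic tissue in the replicate 2 sample stays open, as 16 diencephalic genes held 61 and 81 peaks and gave −0.38 (−0.76 to 0.62). The pattern rested on Tfap2b and Gata3, without which the log2 ratio was −0.085 (−0.39 to 0.41). Apart from tissue in the samples, no biological explanation was tested.

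The neurogenic E-box was found in 5.44% (5.25 to 5.65) of the 50275 distal peaks of replicate 1 without a partner in the equal-length lists, in 2.45% of its shared distal peaks and in 0.717% of the 46468 distal peaks of replicate 2 alone. The equal-length cut removed weak peaks of replicate 1 only. Replicate 2 peaks without a partner, promoters included, numbered 54733 after it and 43427 in the full lists. Peaks of replicate 2 alone thus include weak calls and some with a partner in the full list. Base composition does not account for the difference as a whole, since against replicate 2 peaks drawn to the same GC content the odds ratio was 6.75 (6.09 to 7.48). Peak strength was not matched in that comparison. Sites just under the calling limit of replicate 2 stay open as a source of the E-box difference, since only called peaks could be examined. Shared distal peaks with the lowest replicate 2 signals (3 to 15) had the motif in 2.70% (2.38 to 3.06). The share was 1.85% at signals of 21 to 26 and 2.27% at the highest signals (37 to 114). All of these lay below the 5.44% of replicate 1 peaks alone. The CTCF site was found in 1.09% of replicate 1 peaks alone, 10.9% of its shared ones and 0.689% of replicate 2 peaks alone, and the GATA site was found in 0.487% of replicate 1 and 1.33% of replicate 2 peaks alone. No biological explanation was tested.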
